A study of Mus musculus with 2 samples.

How the data were processed

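The samples were 2 biological replicates of heart tissue from mouse embryos of 13.5 days, per the labels, immunoprecipitated for H3K27ac and sequenced. Nothing in the labels says which animals went into each, beyond their being separate biological replicates from pooled males and females. The deposited files were 4 peak lists on mm10: 1 for each replicate, 1 for both pooled and 1 of replicated peaks. Per the deposited text list of files, each replicate's peaks were derived from that replicate's alignments and 1 other file, the pooled list from both alignments and 2 other files, and the replicated list from the pooled list and both replicates' lists. The peak caller, its version and its threshold are not given in the sources used here. The labels name a possible control experiment, which was not analysed here.

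Each peak has a fold enrichment, a linear ratio, as the authors deposited it, and a −log10 p and a −log10 q that the authors deposited beside it. The lowest −log10 p was 2.00 in replicate 1 and 2.02 in replicate 2, and 85.2% and 87.8% of their peaks had a −log10 q of at least 2. These values were used to describe, rank and filter peaks within a list, and by rank correlation to compare the order of shared regions between the replicates. The files hold no read counts, so depth is unknown and no level of signal was tested between samples; intervals for shares of peaks are exact binomial (Clopper-Pearson) intervals at 95%, cover counting error only and take peaks as independent. No peaks of a list overlapped. For the order of shared peaks, overlapping peaks of both replicates were joined into shared regions, each with the best peak of each list.

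Peaks were compared by overlap of at least 1 bp, with 100 random placements on the same chromosome outside assembly gaps over 1000 bp. The interval code was checked against bedtools 2.31.1 on the 118670 peaks of replicate 1 and differed in 0 peaks and 0 bp. Positions are given on mm10, counted from 1. GENCODE release M21 on the same assembly gave 41162 TSSs of 21644 protein-coding genes on autosomes and X. Peaks on the Y chromosome and on sequences outside the chromosomes entered only the counts per list and the overlaps. A gene's covered length is the number of bp within 5 kb of its TSS under peaks, the highest over its TSSs, from the 76276 top peaks of each replicate. With the window at 10001 bp the measure saturates.

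The 21 gene lists hold 436 different genes, 1 of which (Ahsp) was not matched, and 9 stand in more than 1 list. They are cardiomyocyte contractile genes, cardiac transcription factors, ion channels and conduction, endocardium and endothelium, epicardium, cushion mesenchyme and fibroblasts, smooth muscle and pericytes, neural crest, glia and autonomic neurons, erythroid, leukocyte and macrophage, liver, lung and foregut, forebrain, skeletal muscle, limb patterning, pluripotency and germline, housekeeping, cell cycle, oxidative phosphorylation, glycolysis, and BMP, Notch, Wnt and neuregulin signalling. Each was tested against all other protein-coding genes with a two-sided Fisher's exact test, adjusted by Benjamini-Hochberg over the lists, at an adjusted p of 0.05. For distal regions, a list's mean was placed among 10000 random lists matched in 10 bins on the length of sequence nearest to each gene. Clusters joined distal regions at the distance customary for super-enhancers, and those with at least 10 kb covered were counted as large. For 19 consensus motifs, read on both strands, windows of 500 bp around summits were compared with windows 5 kb to either side that touched no replicated peak.

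Before the data were examined, the 21 lists, the motifs, the tests of the report and the alternatives were fixed, along with the rule for the genes named. In each list these are the 3 members with the most covered bp and up to 2 unmarked members in alphabetical order, and for contractile genes and transcription factors also the 5 with most distal regions. Genome-wide they are the genes nearest to the 15 largest clusters, to the 10 peaks of highest fold and to the 5 highest-ranked peaks of each replicate without a partner. Marked members of lists with few of them, Wnt2b, Alb, the widest peaks, members of the lists below and the genes with the broadest promoters were named after their values were seen. Second lists of 22 erythroid, 20 hepatocyte and 23 lung and foregut genes, with no gene of the first lists, were written after the first lists' values and before their own were seen. Alternatives were a −log10 q of at least 2, the 50000 top peaks, 50% overlap, other windows, other backgrounds, other joining distances, the stronger 50% of the replicated peaks and each replicate alone with as many top peaks as the replicated list.

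On simulated marks over 21644 genes, 98.4% of 5 lists set to 95% marked and 92.0% of 5 lists set to 15% were called in 100 simulations, and 1.82% of the other lists. With distal regions simulated at 3 times the rate near 5 lists, 94.0% of these and 1.88% of the others were called above. In 5000 simulated windows both planted motifs were called and 0 of the others. These windows and their background were drawn with the same base composition. The check therefore does not cover the difference in GC content between summits and flanks. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and samtools 1.23.1; figures used matplotlib 3.10.9.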

Results

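H3K27ac, an acetylation of histone H3 that marks active promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in hearts of mouse embryos 13.5 days of age. The mice were of the B6NCrl strain and the tissue pooled both sexes. The series held 1 group of 2 biological replicates and no second condition, so the comparisons were between the replicates, between kinds of genomic region and between groups of genes within this tissue. Replicate 1 had 118670 peaks and replicate 2 had 115684, a mean of 117177 ± 2111 (SD, n = 2). They covered 77.0 Mb and 77.1 Mb. A list called on both replicates pooled had 135635 peaks, and the authors' list of replicated peaks had 76276, covering 83.3 Mb with a median width of 758 bp. The number of reads behind each list is unknown here, because the files give no counts. Below, a gene is called marked where a replicated peak lay within 1 kb of one of its transcription start sites (TSSs).

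The first comparison asked how far the replicates' peak calls coincided. The strongest sites were shared: all of the 10000 highest-ranked peaks of each replicate overlapped a peak of the other by at least 1 bp. At cardiac promoters such as those of Myh6, the alpha myosin heavy chain, and Tbx5, a transcription factor of heart and forelimb, the replicates' top peaks covered 10001 ± 0 bp and 9923 ± 110 bp of the 10001 bp around the TSS (SD, n = 2). Both genes were named for having the most covered bp, and the measure cannot exceed 10001 bp. Their small SDs are held down by this ceiling and say little about how far the replicates coincide. Over all peaks, 69.9% of those of replicate 1 overlapped replicate 2 (exact 95% binomial interval 69.7% to 70.2%) and 70.9% of those of replicate 2 overlapped replicate 1 (70.6% to 71.2%). Peaks placed at random on their chromosomes overlapped in 5.41% and 5.50% of cases. The share fell with rank, to 90.4% and 91.2% at ranks 25001 to 50000 and to 46.6% and 46.1% at ranks 75001 to 100000. Peaks of replicate 1 without a partner were narrower than those with one (median 231 bp against 508 bp) and had a lower fold enrichment as the authors give it (median 3.07 against 4.36), and in replicate 2 the medians were 235 bp against 526 bp and 3.01 against 4.24. Across 70116 shared regions, which are not independent replicates, the authors' fold enrichment had a Spearman correlation of 0.782 between the lists.

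**Figure D1:**
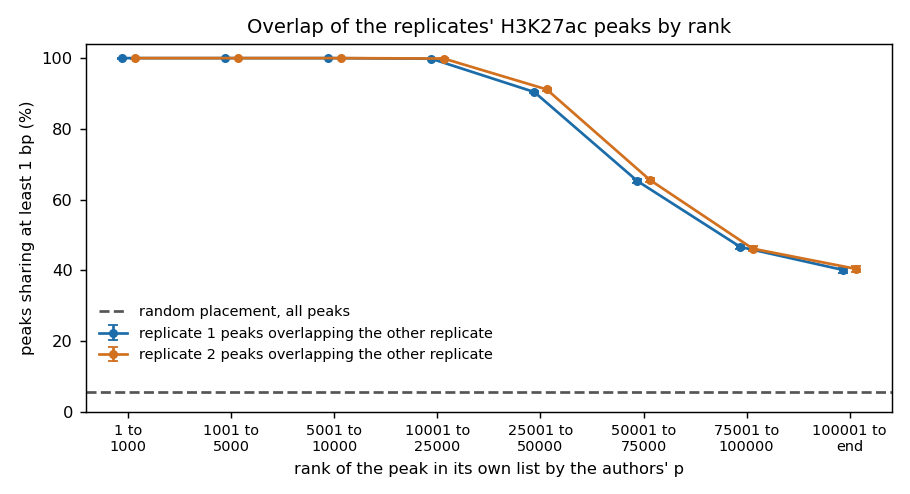
The share of each replicate's peaks (vertical axis, percent) that overlapped the other replicate by at least 1 bp, by the peak's rank in its own list (horizontal axis), with exact 95% intervals; the dashed line is the mean over random placements of all peaks. Both replicates stay at 100% over the first 10000 peaks and fall to 46.6% and 46.1% at ranks 75001 to 100000.

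The highest-ranked peaks found in 1 replicate only stood well down the lists. In replicate 1 the first was at rank 13244, a 490 bp peak within 1 kb of a TSS of Iqub on chromosome 6 (24515018 to 24515507, mm10), followed by peaks in an intron near Ranbp10, in an exon nearest to Foxc1, in an intron near Grb14 and in an intron whose nearest TSS was that of 5530401A14Rik. In replicate 2 the first was at rank 19481, a 410 bp peak within 1 kb of a TSS of Ap3m2 on chromosome 8 (22805152 to 22805561), followed by promoter peaks of Adam5, Mdm1 and the histone gene Hist1h3g and an intronic peak nearest to Tlr4. Per gene, the length covered within 5 kb of the TSS had a Spearman correlation of 0.971 between the replicates across 21644 protein-coding genes, which are not independent. Genes uncovered in both replicates are tied and enter this value, which thus partly reflects the split between covered and uncovered genes. It was not calculated among covered genes alone. The median SD between the replicates was 161 bp over the 13100 genes covered in either. With equal numbers of top peaks, 11275 genes were marked in both replicates and 814 in 1 only.

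The authors' replicated list, derived from the pooled list and both replicates' lists, was then set against the replicates. Its overlap with them follows in part from how it was made and is no independent sign of agreement. All of its 76276 peaks had the coordinates and fold of a peak in the pooled list, and 90.3% (90.1% to 90.5%) overlapped peaks of both replicates. Against the 50000 top peaks of each replicate, fewer than the replicated peaks, the share was 47.5%. A further 3338 overlapped replicate 1 only, 3902 replicate 2 only and 154 neither. The peaks that met both replicates had a median fold of 4.83, against 3.18 and 3.22 for those that met 1 replicate only.

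The next comparison asked where the mark lay. The 10 replicated peaks with the highest authors' fold, from 68.9 to 61.3, were nearest to Sp3, Zc3h4, Arrdc3, Setd1b, Kansl1, Klf7, Kmt5b, Sirt4, Irf2bpl and Brd2. Sp3 and Klf7 encode zinc finger transcription factors, Setd1b and Kmt5b histone methyltransferases, and Brd2 a protein that binds acetylated histones. All of these peaks but the one nearest to Sirt4, 5388 bp away between genes, lay at a promoter. The widest peaks belonged to other genes. The 5 widest, a ranking chosen after the data were seen, were a 21.7 kb peak in an intron nearest to Unc5b, a netrin receptor gene, and promoter peaks of 19.8 kb at Hand2, a transcription factor of the right ventricle, 18.6 kb at Smad7, 18.5 kb at Notch1 and 18.4 kb at Myh7, the beta myosin heavy chain (chromosome 14, 54981011 to 54999415).

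Of the replicated peaks on autosomes and the X chromosome, 19.6% (exact 95% interval 19.3% to 19.9%) lay within 1 kb of a protein-coding TSS. In 100 random placements the mean was 3.27%, the lowest 3.13% and the highest 3.39%. As shares of all these replicated peaks, 46.8% lay outside promoters with their summit in an intron, 29.3% between genes and 4.29% in an exon. Distal regions, with no annotated TSS within 2.5 kb, numbered 48730, or 63.9% of the peaks. Rank separated the kinds: 84.8% of the first 1000 peaks were at promoters and 8.40% distal, against 6.39% and 75.6% beyond rank 50000. With each replicate alone the promoter share was 20.3% and 20.6% among as many top peaks. Counting the TSSs of all annotated genes gave 27.9%.

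Gene lists fixed before the data were examined were then compared with all other protein-coding genes, of which 55.2% were marked (11958 of 21644 genes in all). Every one of the 34 cardiomyocyte contractile genes, the 28 cardiac transcription factors and the 21 genes of cushion mesenchyme and fibroblasts was marked, in the replicated list and in the top peaks of each replicate. Adjusted p was 6.03e-08, 6.92e-07 and 2.14e-05 (two-sided Fisher's exact test, Benjamini-Hochberg over 21 lists; genes are not replicates). Among the contractile genes Myh6, Tpm1 (tropomyosin) and Csrp3 (a Z-disc LIM protein) were covered most in the replicated list, and in the replicates had 10001 ± 0, 9783 ± 221 and 9923 ± 81.3 bp within 5 kb of the TSS (SD, n = 2). Among the transcription factors these were Tbx5 with 9923 ± 110 bp, Gata4 with 9838 ± 64.3 bp and Gata6 with 9860 ± 23.3 bp, against a median over all genes of 648 bp in replicate 1 and 652 bp in replicate 2. In the cushion and fibroblast list Pdgfra, a growth factor receptor, Col1a1, a collagen, and Vcan, the proteoglycan versican, led with 7656 ± 478, 7315 ± 198 and 5580 ± 344 bp.

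Ion channel and conduction genes were marked in 16 of 18 cases (exact test, adjusted p = 0.0047), led by the calcium channel gene Cacna1c with 7606 ± 1498 bp, the gap junction gene Gja1 with 7538 ± 110 bp and the potassium channel gene Kcnh2 with 7009 ± 303 bp; Cntn2 and Hcn1 were not marked. Endocardial and endothelial genes were marked in 22 of 24 cases (exact test, adjusted p = 0.000438), with the most coverage at Notch1 (8000 ± 435 bp), Egfl7 (7781 ± 62.2 bp) and Eng (6433 ± 238 bp), and none at Apln, while Flt4 had 315 bp in replicate 2 and 0 in replicate 1. Smooth muscle and pericyte genes were marked in 12 of 14 cases (exact test, adjusted p = 0.0334), among them Mcam, Cspg4 and Smtn but not the smooth muscle myosin gene Myh11 or Rgs5. This call ended from replicate 2 alone (78.6%, exact test, adjusted p = 0.115), among the stronger 50% of the peaks (71.4%) and against a background without predicted, RIKEN and receptor genes; adjusted p over the 6 alternatives ran from 0.00815 to 0.129 (exact tests). The epicardial list did not differ from other genes, at 9 of 16 (exact test, adjusted p = 1). Its transcription factor genes Wt1, Tcf21 and Tbx18 were covered over 6026 ± 789, 5203 ± 9.19 and 3193 ± 349 bp, whereas Aldh1a2, which makes retinoic acid, had no covered base in either replicate.

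Lists of other tissues were marked less often than other genes. Of 18 limb patterning genes 1 was marked (Sall1), of 22 forebrain genes 2 (Nes and Bcl11b), of 20 pluripotency and germline genes 2 (Dazl and Esrrb), of 16 lung and foregut genes 2 (Foxj1 and Krt18), of 20 liver genes 3 (Foxa3, Trf and Ttr) and of 21 skeletal muscle genes 6. Adjusted p was 2.79e-05, 2.61e-05, 8.29e-05, 0.00084, 0.000604 and 0.0194. From replicate 2 alone 5 of the liver genes were marked, with Foxa1 and Foxa2 added (exact test, adjusted p = 0.0148; 4.15e-05 to 0.0148 over the 6 alternatives). Of the lung and foregut genes 3 were marked from replicate 2 alone and 0 from replicate 1 alone. Within 2.5 kb of a TSS 20% of the germline genes were marked. The unmarked genes included the limb genes Hoxa9, Hoxa10, Alx3 and Alx4, the forebrain genes Foxg1, Arx and Dlx1, the liver genes Afp and Ahsg, the epithelial genes Cdh1 and Cdx1, the germline genes Ddx4 and Dppa3 and the skeletal muscle genes Acta1 and Cacng1. The marked skeletal genes with the most coverage were Ckm, Tnni2 and Tnnt3, with 3567 ± 446, 2698 ± 384 and 2158 ± 445 bp. Coverage within 5 kb can belong to a neighbour: Apoa2, Sftpc, Gdf9 and Nanog had 1588 ± 336, 2235 ± 414, 1895 ± 59.4 and 1519 ± 185 bp there but no replicated peak within 1 kb of a TSS. Pooled by kind, 142 of 155 heart genes were marked (91.6%, exact interval 86.1% to 95.5%) and 16 of 115 genes of other tissues (13.9%, 8.17% to 21.6%). At 3 of those 16 (Actn3, Foxa3 and Trf) the same peak also reached the TSS of another gene.

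**Figure D2:**
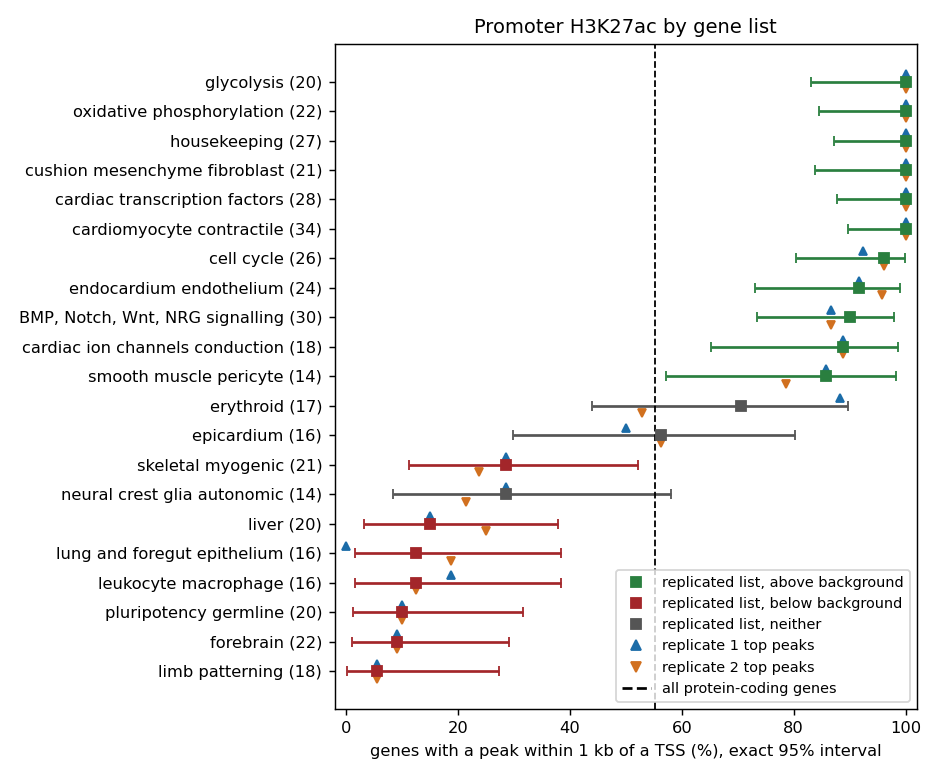
Percent of each list's genes (number in brackets) with a peak within 1 kb of a TSS. Squares with bars are the replicated list with exact 95% intervals, triangles the top peaks of each replicate, and the dashed line all protein-coding genes at 55.2%; the heart lists lie above the line, the epicardium at 56.2% without a call, and the erythroid list runs from 52.9% in replicate 2 to 88.2% in replicate 1.

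Genes of other cells that a heart can hold were marked unevenly. Of 16 leukocyte and macrophage genes 2 were marked (Cd68 and Fcer1g; exact test, adjusted p = 0.00084), and Adgre1 and C1qa had no covered base. Within 2.5 kb of a TSS 25% of this list was marked, and among the stronger 50% of the peaks 0. Of 14 neural crest, glial and autonomic genes 4 were marked (exact test, adjusted p = 0.0648), led by Hand2, which also stands in the cardiac list, with 9613 ± 403 bp; Ascl1 was uncovered in both replicates. This list fell below other genes from replicate 2 alone (21.4%, exact test, adjusted p = 0.0188), among the stronger 50% of the peaks, against the restricted background and without members of other lists; adjusted p over the 6 alternatives ran from 0.0134 to 0.126 (exact tests). The erythroid list was marked in 12 of 17 cases (exact test, adjusted p = 0.243) and was the list in which the replicates were furthest apart, with 88.2% in replicate 1 and 52.9% in replicate 2. From replicate 1 alone it stood above other genes (exact test, adjusted p = 0.00693; 0.00693 to 1 over the 6 alternatives). Hba-a1, an adult alpha-globin gene, was covered over 6273 bp in replicate 1 and 2197 bp in replicate 2, and Slc4a1, the red cell anion exchanger, over 7346 and 5449 bp. Tal1, a transcription factor of blood and endothelium, had 7017 and 7050 bp. Gata1 had no covered base, and Alas2 had 356 bp in replicate 1 only. No test between the replicates is possible with 1 library each.

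**Figure D3:**
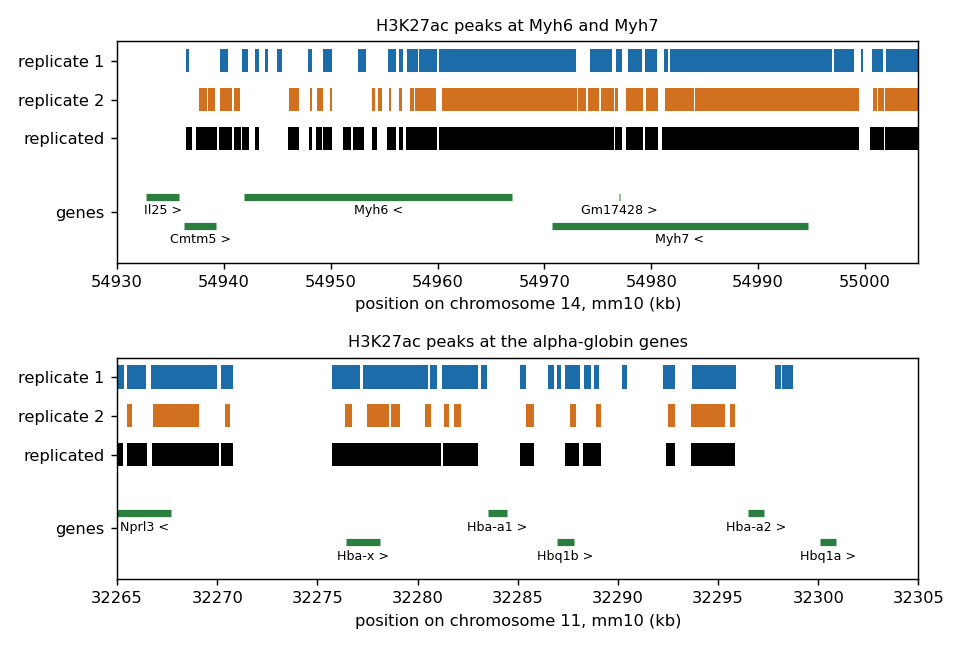
Peaks (bars) on mm10 at Myh6 and Myh7 on chromosome 14 (top, a 75 kb window) and at the alpha-globin genes on chromosome 11 (bottom, a 40 kb window), from equal numbers of top peaks of each replicate and from the replicated list, above protein-coding genes with their direction; horizontal axes are positions in kb. The peaks of replicate 1 and replicate 2 covered 48.0 kb and 49.4 kb of the upper window but 18.4 kb and 8.90 kb of the lower one.

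The reference and process lists were marked throughout or nearly so. All 27 housekeeping genes, 22 genes of oxidative phosphorylation and 20 of glycolysis were marked (exact tests, adjusted p = 8.5e-07, 1.42e-05 and 2.61e-05), as were 25 of 26 cell cycle genes (2.61e-05; not the mitotic kinase gene Bub1) and 27 of 30 genes of BMP, Notch, Wnt and neuregulin signalling (0.000117; not Fgf10, Wnt2 or Wnt2b). Members with wide coverage in these lists were Igf2, a growth factor gene, with 9601 ± 38.9 bp, Actb with 8629 ± 107 bp, the Notch target Hes1 with 8016 ± 161 bp, Notch1 itself with 8000 ± 435 bp, the glucose transporter gene Slc2a1 with 7625 ± 330 bp, Gapdh with 7607 ± 629 bp and the cyclin gene Ccnd2 with 7602 ± 105 bp. In oxidative phosphorylation the most covered was Ppargc1a, a coactivator of mitochondrial genes, with 5943 ± 608 bp. In all, 11 lists stood above other genes, 7 below, and 3 did neither.

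Distal regions were assigned to the nearest protein-coding TSS within 100 kb. The cardiac transcription factors had a mean of 16.6 distal regions per gene, 3.61 times the 4.60 of random lists matched on the length of sequence nearest to the gene, and the contractile genes had 7.50 against 1.95, 3.85 times. Counts of single genes were not matched on that length, which was 666 kb for Foxp1 and 139 kb for Tbx20, so they do not measure density. Foxp1 had 65 distal regions, Tead1 52, Meis1 39, Myocd 35 and Tbx20 26, and all encode transcription regulators. Among the contractile and calcium handling genes, Slc8a1, the sodium-calcium exchanger, had 43, Ryr2, the calcium release channel, 32, Tpm1 and Atp2a2, the calcium pump, 21 each and Ttn, titin, 19. Each replicate's top peaks gave close means for the transcription factors (16.7 and 16.1) and the contractile genes (7.47 and 7.88). The stronger 50% of the peaks, being fewer, gave 6.61 and 3.09. Ion channel genes (8.44 against 3.12), endothelial genes (7.67 against 2.88), signalling genes (8.57 against 4.16), housekeeping genes (2.48 against 1.00) and glycolysis genes (2.55 against 1.10) were also at or over the upper bound of 95% of 10000 random lists. The forebrain list was at the lower bound, with 1.32 against 3.13, and the 13 other lists lay between the bounds. The glycolysis call ended with limits of 50 kb and 250 kb, among the stronger 50% of the peaks and against unmatched random lists, which also ended the housekeeping call. The forebrain call ended with replicate 2 alone (1.45), among the stronger 50% of the peaks and against unmatched lists. Cushion and fibroblast genes (6.38 against 3.93) passed the bound with replicate 2 alone (6.86), within 50 kb and against unmatched lists, and smooth muscle genes (3.86 against 1.77) with either replicate alone (4.29) and within 50 kb. By the median in place of the mean these last lists lay at percentile 100 and 99.5 of random lists, and the forebrain list at 10.4.

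**Figure D4:**
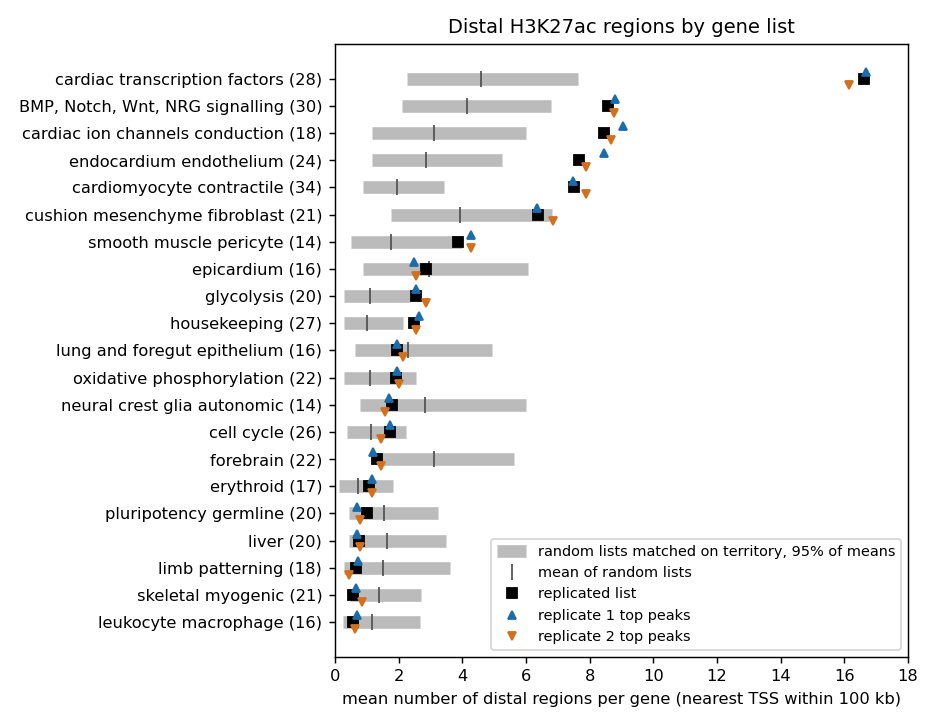
Mean number of distal H3K27ac regions per gene (horizontal axis) for each list (number of genes in brackets). Squares are the replicated list, triangles the top peaks of each replicate, and grey bars hold 95% of the means of 10000 random lists matched on territory; the cardiac transcription factors lie farthest right at 16.6.

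Distal regions were joined at the distance customary for super-enhancers into 19465 clusters, of which 675 covered at least 10 kb. The cluster with the most covered sequence overlapped Msi2, which encodes an RNA-binding protein, on chromosome 11 (88359124 to 88706731), with 99 peaks and 156 kb covered; the top peaks of the replicates covered 126 ± 3.24 kb of it (SD, n = 2). The next overlapped Rbm20, a splicing regulator of titin, on chromosome 19 (53647954 to 53833170) with 83.2 kb, Nfib, a transcription factor gene, with 78.8 kb, Lrrfip1 with 67.8 kb and Creb3l2 with 64.5 kb. The clusters of rank 6 to 15 were nearest to Smad6, Tspan9, Fndc3b, Cux1, Sipa1l2, Palm2, Ski, Cgnl1, Smad7 and Cdh2 and covered 63.8 to 46.9 kb each. Smad6 and Smad7 encode inhibitors of BMP and TGF-beta signalling, Ski a repressor of the same pathway and Cdh2 the N-cadherin of cardiomyocyte junctions. Of the cardiac transcription factors 12 of 28 were nearest to a large cluster, as were 5 of 18 ion channel genes, 7 of 34 contractile genes and 0 of 16 epicardial genes, against 588 of all 21644 protein-coding genes. These counts were not matched on the length of sequence nearest to the gene. Each replicate's top peaks alone gave 455 large clusters, of which 379 of replicate 1 met one of replicate 2. Joining only within 5 kb gave 347.

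Motifs were counted in the 500 bp around the summits of 48726 distal regions and in 77852 flanking windows 5 kb away. Motifs of the TEAD, MEIS and ETS families, whose members act in heart muscle and endothelium, were more frequent at the summits. TEAD occurred in 16.1% against 11.6% (ratio 1.38, 95% interval 1.34 to 1.42), MEIS in 21.1% against 15.7% (1.35, 1.31 to 1.38) and ETS in 33.6% against 24.9% (1.35, 1.33 to 1.37). The AP1 motif had a ratio of 1.29 and the E-box CAGCTG of myogenic regulators, listed as a motif of another tissue, the highest, 1.52 (1.49 to 1.55). Adjusted p for these 5 lay at or under 1.36e-45 (two-sided Fisher's exact test, Benjamini-Hochberg over 19 motifs; windows are not replicates). NKX2-5 passed with a ratio of 1.04 (exact test, adjusted p = 0.0274) and had 0.995 among the stronger 50% of the peaks and 1.02 within 200 bp, where the call ended (adjusted p over the 5 alternatives 1.9e-26 to 0.899, exact tests). OCT-SOX (0.679) and HOX13 (0.664), motifs of other tissues, were less frequent at summits than in flanks. So were TBX (0.881), SOX (0.948) and GATA (0.966), the motif of Gata4 and Gata6. GATA occurred in 60.2% of summit windows against 62.3% of flanks (exact test, adjusted p = 9.42e-14). Most windows of either kind held this short motif, so the share says little about sites that are bound. The GATA ratio was 0.824 within 200 bp of the summit, and its adjusted p over the 5 alternatives ran from 6.53e-105 to 2.14e-10 (exact tests). The TBX and SOX calls ended within 200 bp of the summit, and the SOX call also without replicate 2 (0.973).

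For several motifs the result turned on the background. Distal regions had a mean GC content of 47.6%, against 44.1% in flanks. The GC-matched windows were drawn at random from autosomes and X, away from TSSs and replicated peaks. Flanks lay 5 kb from the summits, so the backgrounds differed in place as well as in GC. A change between them cannot be assigned to GC alone. Against windows matched on GC, MEF2, a muscle regulator motif, had a ratio of 1.72 (1.64 to 1.80; exact test, adjusted p = 4.64e-117), against 1.03 with flanks (exact test, adjusted p = 0.134). GATA, called below flanks at 0.966, was called above GC-matched windows at 1.06 (exact test, adjusted p = 5.73e-29). The HAND E-box had 0.945 in place of 1.02, NKX2-5 a ratio with an interval of 1.16 to 1.24 and FOXA 1.33, and REST was called below at 0.726 (exact test, adjusted p = 0.000179) in place of 0.990 without a call, while TEAD, MEIS, ETS, AP1 and the CAGCTG E-box had ratios of 1.29, 1.15, 1.26, 1.36 and 1.28. The windows of 200 bp were compared with flanks only, not with GC-matched windows, so GC was not accounted for there. Within 200 bp of the summit MEF2 had a ratio of 0.453 to flanks, and among the stronger 50% of the peaks 1.17. Its adjusted p over the 5 alternatives ran from 4.64e-117 to 0.288 (exact tests). Without replicate 1 MEF2 passed the threshold with 1.04, without replicate 2 FOXA with 1.06, and without either CTCF, with 1.34 and 1.36. Within 200 bp CTCF was called below flanks at 0.468 (exact test, adjusted p = 0.000215), SRF below at 0.699 (7.8e-09) and the HAND E-box above at 1.04 (0.00411). Adjusted p over the 5 alternatives ran from 0.000215 to 0.342 for CTCF, 7.8e-09 to 0.968 for SRF and 2.72e-11 to 0.618 for the HAND E-box (exact tests).

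**Figure D5:**
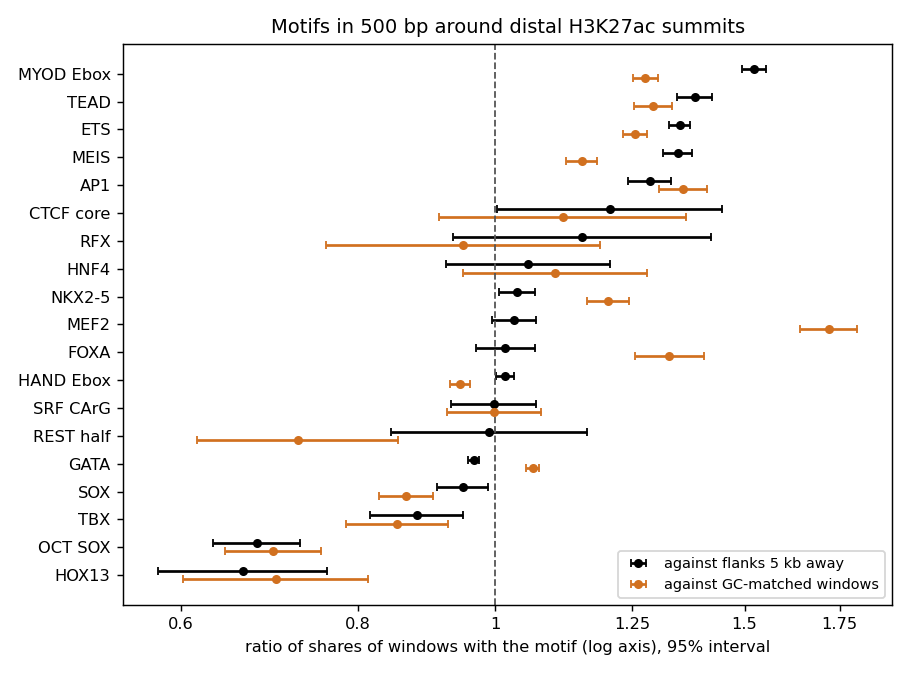
Ratio of the share of distal summit windows with each motif to the share of background windows (horizontal log axis, 95% intervals), against flanks (black) and GC-matched windows (orange). TEAD, MEIS, ETS, AP1 and the MYOD E-box lie above 1 against both, and MEF2 moves from 1.03 to 1.72.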

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

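Peaks that few or none of the comparisons used were counted. The pooled list held 19869 peaks (14.6% of it) that overlapped a peak of neither replicate, of which 154 are in the replicated list and entered its comparisons; the median width of the 19869 was 209 bp, against 399 bp for the whole list, and their median fold 2.49, against 3.22. The replicated list held 6 peaks on sequences outside the assembled chromosomes, which entered the counts and overlaps but no comparison of genes. With no control samples, the counts are given because they are over the 3 that a count of 0 allows, which does not show that such peaks are unusual.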

How the results depend on the processing

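The counts of gene lists above and below other genes ranged from 10 to 12 and from 7 to 8 over their alternatives. The lists above random for distal regions ranged from 6 to 9, and the motifs above background from 6 to 9. All lay within 1.5 times the reported counts. The 9 motifs were above GC-matched windows in place of flanks and included GATA, which was called below flanks. The shares of replicate 1 and replicate 2 peaks that overlapped were 80.8% and 80.5% among the 50000 top peaks and 60.9% and 61.3% with 50% of the peak covered, and that of replicate 1 was 71.8% with a −log10 q of at least 2. The share of replicated peaks that met both replicates was 80.7% against peaks with a −log10 q of at least 2, 47.5% against the 50000 top peaks, which are fewer than the replicated peaks, and 75.3% with 50% covered. The correlation of the order of shared peaks was 0.792 with a −log10 q of at least 2, 0.824 by −log10 p and 0.765 with the widest peak. The share at promoters was 23.5% within 2.5 kb, 27.9% with the TSSs of all genes, both wider definitions, and 20.3% to 20.6% without a replicate. The correlation of covered length was 0.970 within 2 kb and 0.974 with all peaks. Large clusters numbered 347 when joined within 5 kb and 455 to 806 under the other alternatives.

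The epicardial list, which passed no test, moved below other genes at 37.5% among the stronger 50% of the peaks, 50% without replicate 2 and 56.2% against a background without predicted, RIKEN and receptor genes; the erythroid list did so at 52.9% without replicate 1, against 88.2% without replicate 2. Motif ratios crossed 1 against GC-matched windows for GATA (1.06), the HAND E-box (0.945) and RFX (0.949). Within 200 bp they did so for MEF2 (0.453), CTCF (0.468), FOXA (0.947) and REST (1.18). Among the stronger 50% of the peaks they did so for NKX2-5 (0.995), SRF (1.07), the HAND E-box (0.992), FOXA (0.999) and REST (1.13). Without replicate 1 they did so for SRF (1.06) and REST (1.04), and without replicate 2 for SRF (1.04), HNF4 (0.992, against 1.08 without replicate 1) and REST (1.18). The cause was not tested for any of these but the erythroid list, whose difference between the replicates is weighed under other observations. Among the other values of single lists, genes and motifs, 403 were the same, 85 moved, 15 lost their call and 21 gained one. Those that moved were all covered lengths of single genes, 56 with the window cut to 2 kb and 29 with all peaks. A window of 2 kb holds at most 4001 bp, so wide coverage falls there through the change of window itself. Read depth is unknown, so what it limits could not be stated. No paired analysis was possible because there is 1 group.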

Other observations

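The test of the broadest promoters and the tests of differences between the replicates at weakly marked promoters in general were chosen after the results were seen; the other tests were fixed before their values were seen.

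Wide coverage around the TSS was most frequent in the contractile and cardiac transcription factor lists, each compared with all other genes and not with other lists. Among the 500 genes with the most covered bp in the replicated list (at least 6287 bp within 5 kb) were 22 of 34 contractile genes, including Actc1, Myl2, Myl7, Tnnt2 and Ttn, and 18 of 28 cardiac transcription factors, including Nkx2-5, Hand1, Hand2, Tbx20 and Irx4, against 2.31% of all genes. Adjusted p was 5.63e-27 and 2.89e-22 (two-sided Fisher's exact test, Benjamini-Hochberg over 21 lists). Glycolysis followed with 5 of 20 (Aldoa, Eno3, Gapdh, Hk1 and Slc2a1), signalling with 5 of 30, ion channels with 4 of 18 and endothelium with 4 of 24, at adjusted p of 0.000525, 0.0028, 0.0028 and 0.00725. Housekeeping genes, all marked, had 3 of 27 (exact test, adjusted p = 0.0713), and oxidative phosphorylation, all marked, 1 of 22 (0.603). The lists of liver, lung, forebrain, skeletal muscle, limb, germline and leukocyte genes had 0.

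The erythroid list was marked at 15 of 17 promoters in replicate 1 and 9 in replicate 2, with 2785 and 1610 bp covered per gene on average. A candidate explanation is more erythroid cells in replicate 1: in a second list of 22 erythroid genes, none of them in the first lists, 18 had more covered bp in replicate 1 and 2 in replicate 2 (Nfe2 6315 and 4070 bp, Fech 6506 and 5109 bp, Ermap 2267 and 0 bp), and its mean difference of 829 bp lay at percentile 100 of random lists matched on coverage. The same percentile sets the second erythroid list outside the differences between the replicates at promoters of like coverage in general. It is the value already used for erythroid cells, and this reading of it was chosen after the results were seen. The list had 2885 and 2056 bp covered per gene on average in replicate 1 and replicate 2, so it says little about weakly marked promoters. Fetal liver tissue in replicate 1 was not shown. A second list of 20 hepatocyte genes lay at percentile 20.6, under the 50 set against it. That list cannot exclude a small share of liver. Of its genes 16 had equal coverage in both replicates, 2 had more in replicate 1 and 2 in replicate 2. Alb and Afp had no covered base in either replicate. Replicate 2 also marked 16 of the 22, the labels used here name no sort that removes blood, and with 1 group the design names no biological difference that was tested; of the other first lists, cushion and fibroblast genes (3503 and 3736 bp in replicate 1 and replicate 2, percentile 0.69) and ion channels (3720 and 3944 bp, percentile 1.41) lay outside the random bounds in the opposite direction.

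The lung and foregut list was marked at 0 of 16 promoters in replicate 1 and 3 in replicate 2 (Foxj1, Krt18 and Foxa2), with a mean difference in covered bp inside the random bounds (percentile 14.1). A second list of 23 genes lay at percentile 10.7 of matched random lists, within the differences between the replicates at weakly marked promoters in general, with Elf3 and Grhl2 marked in replicate 2 only, while 6 of its genes had more covered bp in replicate 1, 7 in replicate 2 and 10 as much in both. Lung or foregut tissue in replicate 2 was not shown by this, and stays open because the percentile lay between the bounds of 2.5 and 50 set for and against it.

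The X chromosome held 7.78 replicated peaks per Mb, against 23.1 to 45.7 on the autosomes. Fewer genes per Mb do not account for this alone, since X had 1.40 peaks per protein-coding gene and the autosomes 2.26 to 5.68. Fewer active promoters do not either: 38.5% of X genes were marked, against 45.6% to 64.3%, and per marked gene X still had 3.65 peaks, below the 4.96 of the lowest autosome. A lower read number from the single X copy of male embryos may contribute and stays open: the ratio of X to the autosomal median was 0.604 among the stronger 50% of the peaks and 0.566 over all, with X below every autosome in both. The share of males in the pools is not known here, and no cause other than those above was tested, in male or in female embryos.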
